A study of Mus musculus with 6 samples.

How the data were processed

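The series holds 1-colour miRNA arrays of 6 mouse liver samples: 3 HCC and 2 non-tumour (NT) samples of STAM mice and 1 normal liver of a control mouse. Groups were taken from the sample titles and tissue labels. Treated HepG2 cells, which the series design also mentions, were not analysed here. Per the labels, total RNA was extracted with a Qiagen miRNA kit and labelled with the dye Hy5 by a miRCURY LNA labelling kit. Per the file headers, it was hybridised to a Toray mouse miRNA chip (design version 17) with 2 cells per chip, and each array was scanned at 635 nm. The deposited scanner files give, as raw intensity, the pixel median of each spot and of its local background; per the file headers no background subtraction or normalization is recorded. The arrays carry 1 spot for each of 1096 mouse probes, of which 12 name several miRNAs, 39 viral miRNA probes and 1818 blank spots. Probe names are those of the array design and follow an older miRBase release.

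The authors also deposited a table of processed intensity values for the same arrays, with 525 to 633 values per array. Each column has a median of 25. Set against the scanner values, each column is a straight line in the spot intensity (r between 0.99996 and 0.99999 across probes). The spot intensity at which this line gives no signal is near the level of the blank spots. The values are thus linear, not centred per miRNA, background-subtracted and scaled to a common median, and their direction is that of the scanner. Of the tested probes, 348 have a value on all 6 arrays. How the authors chose the background level and which values to leave empty is not given in the sources used here.

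In R 4.3.3 with limma 3.58.1, spot and background intensities were corrected by normexp with an offset of 50 over all spots, and log2 values of 1095 mouse probes were quantile normalized between the 6 arrays. The probe of miR-434-5p, whose spot on HCC 1 was marked not OK, was left out. A probe counted as above background where its spot exceeded the mean plus 2 SD of the array's blank spots, after the highest and lowest 5% of the blanks were left out; 613 probes above background on at least 2 of 6 arrays were tested. Of these, 282 were above background on all 6 arrays, and 511 (83.4%) had a mean signal above the blanks under 50, so that the offset compresses their differences toward 0. MiR-3968 reached the highest scanner value, 16383, on 1 array. Quantile normalization gives equal values to equal ranks, so a group of arrays on which a miRNA holds the same rank shows no spread, as let-7c does in HCC; this understates the spread between samples, and limma offsets variances of 0.

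A limma model with 3 groups was fitted to all 6 arrays (3 residual and 1.63 prior degrees of freedom), and its moderated 2-sided test was adjusted by Benjamini-Hochberg within each comparison at 0.05. Normal liver, with 1 array, adds no residual degree of freedom. Differences are log2 values; n is the number of arrays. Where a miRNA was not above background on any array of a group, a bound is given: the mean of the bright group minus the mean, over the arrays of the dim group, of the higher of the probe's own value and the lowest value among probes above background, as a fold.

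Before the data were examined, 17 lists were fixed: liver-enriched miRNAs, miRNAs known to be raised and known to be lowered in liver cancer, the miR-17-92 clusters, the let-7, miR-29 and miR-30 families, the Dlk1-Dio3 and Sfmbt2 clusters, and markers of mesenchymal and stellate cells, leukocytes, endothelium, erythroid cells, bile duct and epithelium, muscle, pancreas and nerve. They hold 214 entries, older alternative names included. An entry matched the mouse probe of that name, of the name without its arm or, where a RefSeq table gives it as a synonym, of the name without a later added letter; 193 probes matched, counted per list. The rule on synonyms was added once the probe names were known. The lists of raised and lowered miRNAs come from general knowledge of liver cancer and not from these samples. The 15 lists with at least 3 tested members were tested by limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison, with camera's estimated correlation and fry beside it. Members' p-values were also adjusted over the tested members of a list alone, a looser threshold that was not among those fixed beforehand. It is not corrected over the lists or comparisons, so a miRNA that passed it alone is not counted as called. Some lists overlap: of the 18 tested miRNAs lowered in liver cancer, 3 are also mesenchymal markers, 3 liver-enriched, 2 bile duct markers and 1 a leukocyte marker.

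The comparisons, the test, the rule for the miRNAs named and all alternatives but 1 were also fixed before the data were examined. Named miRNAs are, per comparison, those past the threshold without overlap of the arrays (up to 10 per direction), filled by the smallest unadjusted p to 5 per direction where fewer passed, a set of miRNAs fixed by name (miR-122, miR-21, miR-34a, miR-221, miR-222, miR-224, miR-192, miR-194, miR-148a, miR-155, miR-199a, miR-223, miR-142, miR-126 and miR-451), and the up to 4 members of each called list with the smallest unadjusted p. Other members are named as examples, chosen after their values were seen.

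The titles number the STAM mice, so that equal numbers were read as the same mouse, which the labels do not state outright. Deviations from the group means correlated across miRNAs at 0.16 between NT 1 and HCC 1, and at 0.02 and 0.15 between NT 2 and HCC 2-1 and 2-2; with the other NT array each turns its sign, since NT has 2 arrays. The fit with the label number as a replicate block was run as an alternative. Other alternatives were median and upper-quartile scaling over probes above background on all arrays, cyclic loess, a normexp offset of 16, no background correction, subtraction of the blank level with a floor of 1, no filter, a filter on all 6 arrays, the authors' processed values, the label number as a random block, HCC 2-1 and 2-2 averaged, the chip as a block, a fit of the compared groups alone, a trended and robust prior, and each STAM array left out in turn. A scaling made before the offset is added was chosen after seeing the data.

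The test was checked on simulated data for 613 probes with 200 changed, in 20 runs. At a change of 0.5 log2 units, 94.7% of changed probes were recovered for HCC against NT, 88.7% for NT against normal liver and 90.5% for HCC against normal liver, with 3.04%, 3.37% and 3.04% false among those called. With no change, 0.2, 0.1 and 0.2 probes were called on average. Changes were added to the normalized log2 values with independent noise, so the compression by the offset is not covered. With 200 of 613 probes changed, the adjusted threshold is also easier to reach than where few change. The shares recovered are therefore not the power of the test on these data. A list of 15 members shifted by -0.3 had an unadjusted camera p under 0.05 in 20 of 20 runs with either correlation. An unshifted list had such a p in 2 runs with the preset and 0 with the estimated correlation. These p-values were not adjusted over lists, unlike those of the list test in the Results, and simulated members were independent. No comparison had 3 arrays in both groups, so other splits of the samples were not counted. Neighbouring genes were taken by name from a RefSeq table of the assembly GRCm38.p6; no genome build is named in the array files, and no coordinates are given.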

Results

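MicroRNA (miRNA) levels were measured in liver of STAM mice, a model in which streptozotocin and a high-fat diet lead through non-alcoholic steatohepatitis (NASH) to hepatocellular carcinoma (HCC), present at 18 weeks of age according to the sample descriptions. Total RNA of 6 liver samples on a C57BL6 background was hybridised to 1-colour arrays: 3 HCC samples (HCC 1, 2-1 and 2-2), 2 samples of non-tumour liver of STAM mice (NT 1 and 2) and 1 normal liver of a control mouse. The number of arrays limits the precision of every comparison, and the single normal liver has no replicate, so its spread was assumed to equal that of the other groups. P-values measure the spread between these samples, since the labels do not state that HCC 2-1 and 2-2 came from separate animals.

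Of 1096 mouse probes, 403 were above background in normal liver, 478 and 490 in NT 1 and 2, and 487, 526 and 540 in HCC 1, 2-1 and 2-2. A spot above background does not by itself show that its miRNA was present. On at least 2 arrays 51.3% of viral miRNA probes passed, against 56.0% of mouse probes. The 5 brightest miRNAs took 54.3% of the signal in normal liver, 49.1% and 42.4% in NT, and 42.5%, 40.1% and 38.2% in HCC. Across miRNAs, which are not independent replicates, normalized values of array pairs correlated at 0.965 to 0.991. The arrays lay in pairs on 3 chips: normal liver with NT 1, HCC 1 with NT 2, and HCC 2-1 with HCC 2-2. With the chip as a block, HCC minus NT is HCC 1 minus NT 2. NT minus normal liver is then NT 1 minus the normal array, and HCC minus normal liver the sum of both differences, chained through NT. The 1 residual degree of freedom comes from HCC 2-1 and 2-2. A p-value from such single pairs of arrays cannot show that a shift held, so it is given only where a call ended. Scanner gain was 38 for normal liver and both NT arrays, 41 for HCC 1 and 39 for the other HCC arrays, so gain and tumour tissue cannot be told apart. Values are log2 intensities after quantile normalization. Scaling to an equal median in its place moved the median of all 613 tested miRNAs by -0.14 for HCC minus NT, -0.13 for NT minus normal liver and -0.27 for HCC minus normal liver. Upper-quartile scaling moved it by -0.27, -0.34 and -0.61, and in the authors' processed values, over the 348 tested miRNAs that have them on all arrays, the medians were -0.07, 0.33 and 0.32. Where a direction turns relative to these medians, it is said beside the value. Median and upper-quartile scaling, the percentile scalings, each subtract a constant per array from the same log2 values. A value relative to all miRNAs is therefore the same with both, which makes it a single check. Most tested miRNAs are dim and compressed by the offset, and they set that median. Such a turn cannot by itself show that a bright miRNA or list changed direction.

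The comparison of HCC with NT asked how miRNA levels in tumours differ from those in the surrounding liver of the same model. The smallest p in limma's test was that of miR-145, a miRNA of smooth muscle and stellate cells, at 7.66 ± 0.07 in NT (log2 intensity, SD, n = 2) and 6.85 ± 0.09 in HCC (n = 3). The probe shared by miR-199a-3p and miR-199b, known from activated stellate cells, lay at 7.34 ± 0.04 in NT and 6.73 ± 0.11 in HCC. Differences of HCC minus NT were -0.80 (SE 0.07) for miR-145, -0.61 (SE 0.07) for miR-199a-3p/miR-199b, -0.36 (SE 0.04) for miR-195, a miRNA known to restrain the cell cycle, and -0.28 (SE 0.03) for let-7c. Each was lower on all 3 HCC arrays than on both NT arrays. The arrays of HCC and NT did not overlap, in either direction, for 145 of the 613 tested miRNAs, so that position alone says little. On the other side, miR-711 was at 7.02 ± 0.19 in NT and 8.27 ± 0.31 in HCC, a difference of 1.25 (SE 0.21) that was higher on all 3 HCC arrays.

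None of the 613 miRNAs passed limma's adjusted p of 0.05 between HCC and NT, where 56 had an unadjusted p under 0.05 (35 lower and 21 higher in HCC) and 30.7 would by chance. Limma's smallest adjusted p was 0.0645, for miR-145, and over 21 alternative settings it ranged from 2.36e-05 to 0.353 and passed in 5. For let-7c, miR-195 and miR-199a-3p/miR-199b limma's adjusted p was 0.0920, for miR-142-5p (difference -0.36, lower on all HCC arrays) 0.194, and for miR-711 0.236. The next higher miRNAs, miR-149* (0.69), miR-1247* (0.47), miR-5115 (0.33) and miR-128-2* (0.19), were higher on all 3 HCC arrays and did not pass. Over the alternatives, miR-711 and miR-199a-3p/miR-199b passed in 3 (smallest adjusted p 1.80e-10 and 0.00111), and miR-149*, miR-1247* and miR-195 in 2 (3.81e-05, 0.0387 and 0.0101). MiR-26a and miR-31, described with their lists, also passed in 2 (0.0179 and 0.000101). With limma's trended and robust prior, miR-711 and miR-1247* rose and miR-145 fell, at adjusted p of 0.0150, 0.0387 and 0.0381. The other passes of miR-711, its smallest adjusted p among them, and both passes of miR-149* came from median and upper-quartile scaling. These percentile scalings are a single check of a direction, not separate ones. Within chip 2, the sole chip that held both tissues, HCC 1 minus NT 2 was -0.76 for miR-145, -0.71 for miR-199a-3p/miR-199b, -0.25 for let-7c and 0.79 for miR-711. These are also the estimates with the chip as a block.

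Among miRNAs always to be named, miR-122, the dominant miRNA of hepatocytes, was at 12.52 ± 0.19 in NT and 12.21 ± 0.54 in HCC (difference -0.30, limma's adjusted p 0.837). Its HCC arrays overlapped those of NT: HCC 1 was at 11.61 and HCC 2-2 at 12.65. With median and upper-quartile scaling, miR-122 was called lower in HCC, at -0.59 (adjusted p 0.0213) and -0.71 (adjusted p 0.00433). Over all 21 alternatives its difference ranged from -0.93 to -5.33e-15, which is no difference. MiR-21, a miRNA widely raised in tumours and fibrosis, was at 10.88 ± 0.15 in NT and 10.32 ± 0.19 in HCC, lower on all HCC arrays (-0.56, adjusted p 0.424), but 0.09 above the median of all miRNAs with both percentile scalings. Differences that did not pass were also seen for miR-34a, a target of p53 (-0.58), miR-221 (0.17, higher on all HCC arrays), miR-222 (0.03), miR-155 (-0.03), miR-199a-5p (-0.26), miR-223 (-0.35), miR-142-3p (-0.13), miR-192 (-0.07, but 0.18 above all miRNAs with both percentile scalings), miR-148a (-0.19), miR-126-5p (-0.35), miR-126-3p of endothelium (-0.32) and miR-451 of red blood cells (-0.08, but 0.26 above all miRNAs with both percentile scalings). MiR-34a passed as lower with median and upper-quartile scaling (-0.57 and -0.70, adjusted p 0.0110 and 0.00460). Within chip 2 the direction turned for miR-34a (0.19), miR-148a (0.10), miR-192 (0.09), miR-451 (0.09) and miR-222 (-0.04). Other differences there were -0.78 for miR-122, -0.35 for miR-21, -0.72 for miR-126-3p, -0.14 for miR-155 and -0.02 for miR-142-3p. MiR-224 was not above background on enough arrays to be tested.

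As groups, 8 of 15 tested lists shifted between HCC and NT in limma's camera test with its preset correlation, 7 lower and 1 higher. None did with an estimated correlation, and 1 did in fry. With median or upper-quartile scaling 3 of the 8 were kept: miRNAs lowered in liver cancer, the miR-17-92 clusters and bile duct markers. Relative to all miRNAs, both scalings put the median at -0.13 for miRNAs lowered in liver cancer, -0.04 for liver-enriched miRNAs, -0.07 for leukocyte and -0.10 for mesenchymal markers. The list of miRNAs known to be lowered in liver cancer fell: 17 of its 18 tested members were lower in HCC, with a median of -0.23 (camera adjusted p 1.22e-07, fry adjusted p 0.00806, and adjusted p = 0.121 with an estimated correlation). No member passed over all miRNAs. Adjusted over the list alone, a looser threshold that makes no call, 4 did: miR-145, miR-195, miR-199a-3p/miR-199b and miR-26a (-0.60). The exception in direction was miR-378 (0.38). Within chip 2 the list's median was -0.25. The 15 miRNAs known to be raised in liver cancer did not shift: 9 were higher and 6 lower, and camera's adjusted p was 0.986. The median was 0.02 but the mean -0.04, and camera pointed down and fry up. The median was -0.11 with median scaling, 0.03 above all miRNAs there.

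The liver-enriched miRNAs fell as a list, with 11 of 12 lower in HCC and a median of -0.16 (camera adjusted p 0.00136, and adjusted p = 0.424 with an estimated correlation). None passed over all or adjusted over the list alone. MiR-194 differed by -0.31, though 0.07 above the all-miRNA median with both percentile scalings, miR-101a by -0.21, miR-365 by -0.10 and miR-455 by -0.07. This call ended without NT 1 (median -0.07, adjusted p 0.343) and within chip 2 (-0.04, adjusted p 0.630 with the chip as a block); the median was -0.10 without HCC 1 and -0.29 without NT 2.

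The let-7 family, miRNAs of differentiated cells, fell with 8 of 9 members lower and a median of -0.28 (camera adjusted p 0.000531, and adjusted p = 0.339 with an estimated correlation). It lay 0.06 above the median of all miRNAs with median and upper-quartile scaling. Dim probes compressed by the offset set that median, so this cannot show that the direction of let-7 turned. Adjusted over the list alone, let-7c and let-7b (-0.31, but 0.03 above all miRNAs with both percentile scalings) passed, and let-7a and let-7f (-0.31 each, but 0.06 and 0.08 above all miRNAs with those scalings) did not. Within chip 2 the family's median was -0.33, and without HCC 1 it was -0.18. The let-7 call ended with the blank level subtracted (adjusted p 0.122) and in the authors' values (0.157). All 5 members of the miR-30 family were lower, led by miR-30d (-0.44) and miR-30b (-0.40), before miR-30c (-0.20, or -0.11 within chip 2) and miR-30a (-0.17), which lay 0.09 and 0.06 above all miRNAs with both percentile scalings. The family had a median of -0.20 (camera adjusted p 0.0109, and adjusted p = 0.488 with an estimated correlation), which turned to 0.06 above the all-miRNA median with both percentile scalings. The same limit holds for this median and for the miR-30 members. None passed adjusted over the list alone. The miR-30 call ended without NT 1 (-0.09, adjusted p 0.153), without HCC 1 (-0.16, adjusted p 0.0977) and with the chip as a block (-0.19, adjusted p 0.0618). It also ended with cyclic loess (-0.12, adjusted p 0.155), the blank level subtracted (0.122) and the authors' values (adjusted p 0.170). Its median was -0.33 without NT 2 and -0.32 without HCC 2-2. The miR-17-92 and paralogous clusters, known to promote proliferation, were the list that rose: 10 of 13 members were higher, with a median of 0.08 that turned to -0.09 with upper-quartile scaling (0.17 above that scaling's all-miRNA median). Camera's adjusted p was 0.0499, and adjusted p = 0.488 with an estimated correlation. MiR-106a (0.23, but 0.04 within chip 2) and miR-93 (0.15) were higher on all HCC arrays, as was miR-18a (0.08, or 0.05 within chip 2), with miR-20b at 0.24 (-0.01 within chip 2), and none passed adjusted over the list alone. The miR-17-92 call was kept in 7 of 22 alternatives, and not with HCC 2-1 and 2-2 averaged. Within chip 2 the median was 0.03 (adjusted p 0.795), and with the label number as a replicate block the adjusted p was 0.0613. The call was also lost without NT 1 (median 0.01, adjusted p 0.328), NT 2 (adjusted p 0.0571), HCC 2-1 (adjusted p 0.0666) and HCC 2-2 (0.05, adjusted p 0.454).

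Of the markers of other cell types, the leukocyte, mesenchymal and bile duct lists were called lower in HCC with the preset correlation. All 8 tested leukocyte miRNAs were lower, with a median of -0.12 (camera adjusted p 0.000531, and adjusted p = 0.278 with an estimated correlation). MiR-142-5p passed adjusted over the list alone, and miR-146a (-0.18, or -0.08 within chip 2) and miR-146b (-0.10) did not. The median was -0.11 within chip 2, and the call ended without NT 2 (-0.11, adjusted p 0.0666). Mesenchymal and stellate cell markers fell with 7 of 8 lower and a median of -0.17 (camera adjusted p 0.00143, and adjusted p = 0.278 with an estimated correlation). MiR-145 and miR-199a-3p/miR-199b passed adjusted over the list alone, and miR-143, whose gene neighbours that of miR-145 in the mouse assembly GRCm38.p6, differed by -0.36. This median was -0.16 within chip 2 (adjusted p 0.226 with the chip as a block) and -0.26 without NT 1. Bile duct and epithelial markers had 6 of 8 members lower and a median of -0.18 (camera adjusted p 0.0333, and adjusted p = 0.488 with an estimated correlation), led by miR-31 (-0.66), miR-200a (-0.25) and miR-200b (-0.25), with 0 passing adjusted over the list alone. That call ended with the label number as a replicate block (adjusted p 0.0557), with the chip as a block (-0.20, adjusted p 0.226), and without NT 1 (adjusted p 0.0625), NT 2 (0.0571), HCC 1 (0.120) or HCC 2-1 (-0.10, adjusted p 0.152). Endothelial (median -0.32, adjusted p 0.319) and erythroid markers (-0.02, adjusted p 0.567) were not called, nor was the miR-29 family (-0.04, adjusted p 0.595), whose median lay 0.21 above that of all miRNAs with both percentile scalings. Neural markers (median 0.02, adjusted p 0.319; 0.01 below the all-miRNA median with the percentile scalings) and the Sfmbt2 cluster (-0.01, adjusted p 0.465; level with that median in the authors' values) were not called either. The Dlk1-Dio3 imprinted cluster had 16 of 22 members higher and a median of 0.03 (adjusted p 0.260), which was -0.13 with median scaling, 0.01 above all miRNAs there. Its median was 0.04 within chip 2, and it was called without HCC 2-2 (adjusted p 0.0169). Of muscle and pancreas markers 1 each was tested, miR-133b (0.02) and miR-375 (-0.11).

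**Figure D1:**
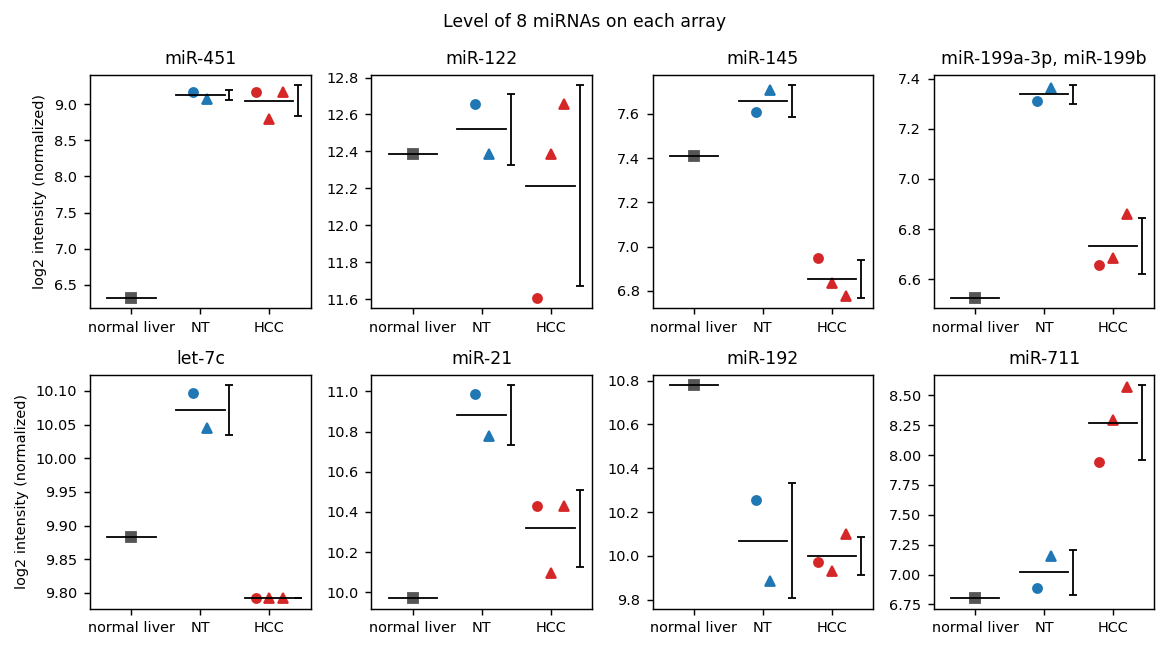
Normalized log2 intensity (y axis) of 8 miRNAs in normal liver, NT and HCC (x axis); points are arrays (square, normal liver; circles, label number 1; triangles, label number 2), horizontal lines are group means and bars beside them are 1 SD. MiR-451 sat at 6.32 in normal liver and at 9.12 and 9.05 on average in NT and HCC, and miR-145 at 7.66 in NT and 6.85 in HCC. Relative to all miRNAs, the lower miR-21 in HCC than NT and the lower miR-192 in HCC than normal liver turn with the percentile scalings. These scalings are a single check there, against a median set by dim probes. MiR-122 in NT against normal liver turns with several settings.

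The comparison of NT with normal liver asked what differs in STAM liver outside the tumours. MiR-451, an abundant miRNA of red blood cells, rose: it was at 6.32 in normal liver and at 9.12 ± 0.07 in NT (n = 2), a difference of 2.80 (SE 0.18, limma's adjusted p 0.0228), higher on both NT arrays. This is 6.98-fold, a value compressed by the offset of 50, since the signal in normal liver lay below it; the difference was 4.88 in the authors' values, to which no offset was added here. MiR-451 was the single miRNA of 613 to pass; 77 had an unadjusted p under 0.05, 34 higher and 43 lower in NT. MiR-199a-3p/miR-199b (0.81, SE 0.10), miR-223 of neutrophils and macrophages (1.04, SE 0.22), miR-34a (1.01, SE 0.45) and miR-21 (0.91, SE 0.18) were higher on both NT arrays without passing, with adjusted p of 0.176, 0.295, 0.434 and 0.295. On the lower side without passing were miR-30a (-0.83, SE 0.24), miR-192 (-0.71, SE 0.17), known from hepatocytes, gut and kidney, and miR-148a (-0.61, SE 0.17). Both NT arrays lay on the same side of the normal array for 440 of the 613 miRNAs, so that position alone says little.

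Signal above the blank spots for miR-451 was 12.8 in normal liver against 406 and 526 in NT. Within chip 1, which held normal liver and NT 1, the difference was 2.85. The direction of miR-451 held in all 19 alternatives, with values from 2.52 to 4.88 (the authors' processed values), and the call in 13. It ended with the chip as a block (adjusted p 0.436), in a fit of NT and normal liver alone (0.450), and without NT 1 (0.142), NT 2 (0.342), HCC 1 (0.101) or HCC 2-2 (0.110). Next by p, and not passing, were miR-690 (0.27, turning to -0.48 with cyclic loess and, relative to all miRNAs, to -0.13 in the authors' values), miR-195 (0.33) and miR-342-3p (0.49) on the higher side. On the lower side these were miR-193b (-0.33), miR-466i-5p (-0.25), miR-3069-3p (-0.39), miR-30c (-0.47) and miR-3067 (-0.29). The difference of miR-690 was the same, 0.27, with the chip as a block, since NT 1, NT 2 and HCC 1 held equal values. As for let-7c, quantile normalization thus understates its spread, on which its small p rests. With limma's trended and robust prior, 5 passed: miR-451, miR-199a-3p/miR-199b, miR-342-3p and miR-223 rose and miR-3067 fell. MiR-194 (-0.51), miR-122 (0.14, 0.27 within chip 1, turning to -0.65 with cyclic loess and, relative to all miRNAs, to -0.27 in the authors' values), miR-126-3p (0.53), miR-126-5p (0.16, or 0.31 within chip 1), miR-199a-5p (0.24, or 0.10 within chip 1), miR-142-3p (0.25), miR-142-5p (0.35) and miR-221 (-0.01, but 0.29 above all miRNAs with both percentile scalings) did not pass. MiR-21, miR-34a and miR-223 passed as higher with median and upper-quartile scaling. Over the alternatives, miR-223 passed in 4, miR-199a-3p/miR-199b in 3, and miR-126-3p, miR-210, miR-222 and let-7i in 1. MiR-222, miR-155, miR-181a and the probe shared by miR-486 and miR-3107 were not above background in normal liver. The bound takes the NT mean over the higher of the dim probe's own level and the dimmest level measured above background. For these probes it equalled the fitted difference, so it sets no lower limit. It was 1.17-fold, 1.07-fold, 1.22-fold and 1.09-fold higher in NT, with limma's adjusted p of 0.295, 0.605, 0.295 and 0.449.

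In the list test 7 of 15 lists shifted between NT and normal liver, 5 higher and 2 lower. None did with an estimated correlation, where the smallest adjusted p was 0.341, nor in fry. With median or upper-quartile scaling 5 of the 7 were kept, the higher ones. Relative to all miRNAs, both scalings put the median at -0.08 for liver-enriched miRNAs, 0.57 for let-7 and 0.43 for mesenchymal markers. Liver-enriched miRNAs fell, with 10 of 12 lower and a median of -0.31 (camera adjusted p 0.000584, and adjusted p = 0.341 with an estimated correlation). Adjusted over the list alone miR-193b passed, and miR-193 differed by -0.37 (-0.24 within chip 1). The list's median was -0.17 within chip 1 and -0.17 without NT 2. The call ended with median and upper-quartile scaling (adjusted p 0.0865 and 0.122). The miR-30 family fell with 4 of 5 lower and a median of -0.34 (camera adjusted p 0.0135, and adjusted p = 0.471 with an estimated correlation), which turned to 0.05 above the all-miRNA median with both percentile scalings (adjusted p 0.776 and 0.728). Adjusted over the list alone miR-30c passed, and miR-30e (-0.33) and miR-30d (-0.34), 0.12 and 0.05 above all miRNAs with both percentile scalings, did not. Within chip 1 the family's median was -0.28, no longer called with the chip as a block (adjusted p 0.0865), nor with the blank level subtracted (0.285) or in the authors' values (0.307).

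Leukocyte markers rose, with 7 of 8 higher in NT and a median of 0.20 that became -0.18 with upper-quartile scaling, 0.17 above all miRNAs there (camera adjusted p 0.00278, and adjusted p = 0.341 with an estimated correlation). Adjusted over the list alone miR-142-5p, miR-223 and miR-342-3p passed, and within chip 1 the median was 0.22. All 8 mesenchymal and stellate cell markers were higher, with a median of 0.19 (camera adjusted p 0.0115, and adjusted p = 0.341 with an estimated correlation), 0.17 within chip 1. This call ended with the blank level subtracted (0.40, adjusted p 0.245). MiR-199a-3p/miR-199b passed adjusted over the list alone, and miR-145 (0.25) and miR-143 (0.31, or 0.09 within chip 1) did not. The let-7 family rose with 8 of 9 higher and a median of 0.18 (camera adjusted p 0.00987, and adjusted p = 0.341 with an estimated correlation), led by let-7i (0.46), before let-7b (0.20, but -0.02 relative to all miRNAs with the blank level subtracted and arrays scaled before the offset), let-7c (0.19) and miR-98 (0.14). None passed adjusted over the list alone, the median was 0.21 within chip 1, and the call ended without NT 1 (0.11, adjusted p 0.0586). It also ended with no background correction (adjusted p 0.0802), the blank level subtracted (0.424, or 0.312 with arrays scaled before the offset) and the authors' values (adjusted p 0.170). Of miRNAs known to be raised in liver cancer, 13 of 15 were higher in NT, with a median of 0.09 that became -0.03 and -0.24 with the percentile scalings, 0.11 above all miRNAs in each (camera adjusted p 0.00278, and adjusted p = 0.341 with an estimated correlation). Besides miR-21 and miR-34a, miR-210, a miRNA induced by hypoxia, was higher (0.58). None passed adjusted over the list alone, and the median within chip 1 was 0.06. The 3 erythroid markers had a median of 0.12, below 0 (-0.06 and -0.27) with the percentile scalings and 0.08 above all miRNAs there, and a mean of 1.00 that rested on miR-451, the member that passed over all and adjusted over the list alone (camera adjusted p 0.00987, and adjusted p = 0.341 with an estimated correlation). MiR-144 differed by 0.07. The erythroid call ended with the chip as a block (0.13 within chip 1, adjusted p 0.0771).

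The remaining lists were not called between NT and normal liver. MiRNAs known to be lowered in liver cancer had a median of 0.13, -0.22 with upper-quartile scaling but 0.13 above all miRNAs there (adjusted p 0.140). It was -0.04 relative to all miRNAs with the blank level subtracted and arrays scaled before the offset. Of this list miR-199a-3p/miR-199b, miR-195 and miR-223 passed adjusted over the list alone. The test of this list, pointing up, passed with median and upper-quartile scaling (adjusted p 0.000845 and 0.00506) and without NT 2 (0.0453). Medians were -0.05 for the miR-17-92 clusters (adjusted p 0.540, and 0.17 above all miRNAs with the percentile scalings), 0.13 for the miR-29 family (0.690) and 0.16 for endothelial markers (0.236). The miR-29 family was called with median scaling (0.63 above all miRNAs, adjusted p 0.0243), and endothelial markers with median and upper-quartile scaling and in a fit of NT and normal liver alone (adjusted p 0.00852, 0.0109 and 0.0456). Bile duct markers had a median of 0.06 but a mean of -0.03 (adjusted p 0.571). The Dlk1-Dio3 cluster had a median of 0.02 but a mean of -0.03, with the test pointing down (adjusted p 0.921), and lay at -0.58 relative to all miRNAs in the authors' values. Neural markers (-0.01, adjusted p 0.559; 0.01 with the blank level subtracted and arrays scaled before the offset) and the Sfmbt2 cluster (-0.01, adjusted p 0.644; level with all miRNAs with cyclic loess) were not called. MiR-133b differed by 0.08 and miR-375 by 0.12.

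The comparison of HCC with normal liver shares the normal array with the one above, so that the values of both carry the same error of that array. MiR-451 rose, to 9.05 ± 0.22 in HCC (n = 3) from 6.32, a difference of 2.73 (SE 0.17, limma's adjusted p 0.0198), higher on all 3 HCC arrays. This is 6.61-fold, compressed in the same way; the authors' values gave 4.76. MiR-451 was the single miRNA to pass; 99 had an unadjusted p under 0.05, 47 higher and 52 lower. MiR-30a (-1.01, SE 0.23), miR-194 (-0.82, SE 0.18), miR-148a (-0.80, SE 0.16) and miR-192 (-0.78, SE 0.16) were lower on all HCC arrays, each with an adjusted p of 0.181; miR-192 and miR-194 lay 0.02 and 0.05 above the median of all miRNAs with both percentile scalings. MiR-711 (1.47, SE 0.26, adjusted p 0.181) and miR-210 (0.77, SE 0.23, adjusted p 0.248) were higher on all HCC arrays. All 3 HCC arrays lay on the same side of the normal array for 391 of the 613 miRNAs, so that position alone says little.

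The signal of miR-451 above the blank spots was 591, 445 and 786 in HCC. Its difference kept its direction in all 19 alternatives (2.55 to 4.76) and its call in 13. The call ended with the chip as a block (2.94, adjusted p 0.570), in a fit of HCC and normal liver alone (0.0892), and without NT 1 (0.0829), NT 2 (0.0995), HCC 1 (0.118) or HCC 2-2 (0.185). No chip held HCC with normal liver, so no value within a chip exists here. Next by p and not passing were miR-690 (0.27, turning to -0.59 with cyclic loess and, relative to all miRNAs, to -0.53 in the authors' values), miR-296-5p (0.43) and miR-222 (0.25) on the higher side. On the lower side were miR-30c (-0.67), miR-193b (-0.41), miR-145 (-0.55, but level with all miRNAs with both percentile scalings), miR-1843b-5p (-0.20) and miR-5112 (-0.52). The spread of miR-690 is understated here too. With limma's trended and robust prior 8 passed, among them miR-711 (adjusted p 0.0103), miR-193b (0.0103) and miR-1843b-5p (0.0473). MiR-21 (0.35), miR-34a (0.43), miR-223 (0.69) and miR-122 (-0.17) did not pass, with adjusted p of 0.397, 0.665, 0.260 and 0.872. MiR-21 passed as higher with both percentile scalings, and miR-34a and miR-223 with median scaling. Upper-quartile scaling, which called 484 miRNAs lower, called miR-122 lower as well (-0.35 relative to all miRNAs, adjusted p 0.000688). The difference of miR-122 was -1.22 with cyclic loess and 0.09 without HCC 1. Over the alternatives miR-711 passed in 4, miR-1843b-5p in 3, and miR-30a, miR-148a, miR-193b, miR-203, miR-210 and miR-223 in 2. Passing in 1 were miR-126-3p, miR-222 and miR-301a, and also miR-145, miR-192, miR-194, miR-30c, miR-30d, miR-365, miR-99a and miR-5112. With the chip as a block, the differences were 0.66 for miR-21, 1.42 for miR-34a, 0.32 for miR-223 and -0.51 for miR-122. MiR-221 (0.16), miR-199a-3p/miR-199b (0.21), miR-142-3p (0.12), miR-126-3p (0.21) and miR-126-5p (-0.20) did not pass, nor did miR-199a-5p (-0.02) and miR-142-5p (-0.0027). Relative to all miRNAs, miR-126-5p, miR-199a-5p and miR-142-5p lay 0.35, 0.25 and 0.26 higher with both percentile scalings, and miR-126-3p at -0.13 with the blank level subtracted and arrays scaled before the offset. The chip block also turned miR-126-3p (-0.19), gave 0.08 for miR-199a-3p/miR-199b, 0.26 for miR-142-3p, -0.19 for miR-199a-5p and -0.02 for miR-142-5p, as well as 0.87 for miR-711, 0.16 for miR-222, -0.44 for miR-192, -0.36 for miR-148a and -0.26 for miR-5112. The same bound again equalled the fitted difference and set no lower limit. It put miR-222, miR-155, miR-181a and miR-486/miR-3107 at 1.19-fold, 1.04-fold, 1.17-fold and 1.07-fold higher in HCC, with limma's adjusted p of 0.181, 0.693, 0.260 and 0.448.

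Between HCC and normal liver 5 of 15 lists shifted, 3 lower and 2 higher. None did with an estimated correlation, where the smallest adjusted p was 0.378, nor in fry. Median scaling kept 3 of the 5 (liver-enriched, raised in liver cancer and erythroid), and upper-quartile scaling 1, the erythroid markers. Liver-enriched miRNAs fell, with 11 of 12 lower and a median of -0.42 (camera adjusted p 1.57e-06, and adjusted p = 0.378 with an estimated correlation). Of these, 8 passed adjusted over the list alone, and with the chip as a block the median was -0.26. MiR-365 differed by -0.20, though 0.02 above all miRNAs with both percentile scalings. The list's median was -0.12 relative to all miRNAs with both, and the call ended with upper-quartile scaling (adjusted p 0.0608). All 5 miR-30 members were lower, with a median of -0.67 (camera adjusted p 0.000705, and adjusted p = 0.506 with an estimated correlation), -0.47 with the chip as a block. It was level with all miRNAs with both percentile scalings (adjusted p 0.797 and 0.692), and the call also ended in the authors' values (adjusted p 0.105). MiR-30a, miR-30c, miR-30d (-0.78) and miR-30e (-0.40) passed adjusted over the list alone, and miR-30e lay 0.39 above all miRNAs with both percentile scalings. MiRNAs known to be lowered in liver cancer fell, with 15 of 18 lower and a median of -0.21 (camera adjusted p 0.0407, and adjusted p = 0.378 with an estimated correlation), which turned to 0.10 above all miRNAs with both percentile scalings (adjusted p 0.489 and 0.692). MiR-145 passed adjusted over the list alone, miR-203 differed by -0.84 and miR-99a by -0.55 (-0.10 with the chip as a block, and 0.06 above all miRNAs with both percentile scalings), and miR-223 was on the other side. That call ended with the chip as a block (-0.12, adjusted p 0.185) and without NT 2 (0.0646), HCC 2-1 (0.0570) or HCC 2-2 (0.0592). It also ended with no background correction (0.0501), the blank level subtracted (0.141), no filter (0.0604), the filter on all arrays (0.166), the authors' values (0.110) and a fit of these groups alone (0.0559).

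Of miRNAs known to be raised in liver cancer, 14 of 15 were higher in HCC than in normal liver, with a median of 0.19 that became -0.07 and -0.40 with the percentile scalings, 0.21 above all miRNAs in each (camera adjusted p 0.00379, and adjusted p = 0.378 with an estimated correlation). None passed adjusted over the list alone, and miR-301a differed by 0.31 (0.61 with the chip as a block). The call ended with upper-quartile scaling (adjusted p 0.0608), the filter on all arrays (0.0827) and the chip as a block (0.06, adjusted p 0.185), and the median was 0.12 without HCC 2-1. Erythroid markers had a median of 0.10, -0.21 and -0.55 with the percentile scalings and 0.06 above all miRNAs there, and a mean of 0.96 that rested on miR-451, which passed over all and adjusted over the list alone (camera adjusted p 0.0292, and adjusted p = 0.510 with an estimated correlation). MiR-144 differed by 0.05 (-0.02 with the chip as a block). The erythroid call ended with the chip as a block (0.09, adjusted p 0.244), in a fit of these groups alone (0.0559) and without NT 1 (0.0571), NT 2 (0.0646) or HCC 2-2 (0.0901).

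Not called between HCC and normal liver were let-7 (median -0.09, adjusted p 0.744), the miR-29 family (-0.25, adjusted p 0.992) and the miR-17-92 clusters (0.06, adjusted p 0.731). With median scaling these 3 were called higher, 0.61, 0.53 and 0.46 above all miRNAs (adjusted p 2.87e-05, 0.0322 and 0.0288), and let-7 was also called with upper-quartile scaling (adjusted p 0.000441). With the blank level subtracted and arrays scaled before the offset, the medians were -0.06 for miR-17-92, -0.07 for mesenchymal and -0.16 for endothelial markers. Leukocyte markers (0.05, adjusted p 0.446) were not called, though miR-146a and miR-342-3p passed adjusted over the list alone. Mesenchymal markers had a median of 0.01 but a mean of -0.02, with the test pointing down (adjusted p 0.992). They were called higher with median scaling, 0.38 above all miRNAs (adjusted p 0.0469). Of them miR-145 passed adjusted over the list alone. Endothelial markers (0.09, adjusted p 0.744) and bile duct markers (-0.01, mean -0.21, adjusted p 0.731) were not called. Neural markers had a median of 0.01, a mean of -0.01 and a test pointing down (adjusted p 0.992), and lay at -0.05 relative to all miRNAs with both percentile scalings. The Dlk1-Dio3 cluster had a median of 0.03, a mean of -0.01 and a test pointing up (adjusted p 0.731), and lay at -0.02 relative to all miRNAs with these scalings. The Sfmbt2 cluster had a median of -0.04 (adjusted p 0.446). MiR-133b differed by 0.10 and miR-375 by 0.01.

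**Figure D2:**
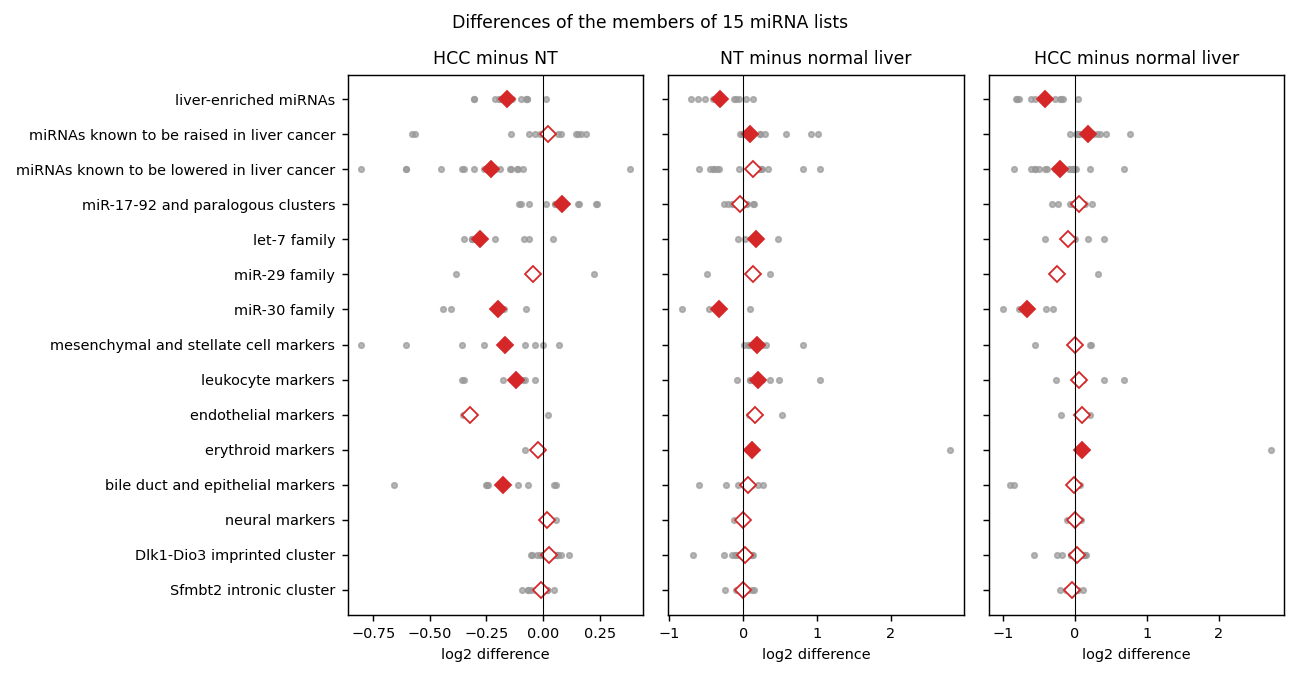
Log2 differences (x axis) of the members (grey points) of 15 miRNA lists (y axis) for HCC minus NT, NT minus normal liver and HCC minus normal liver; diamonds are list medians, filled where camera with its preset correlation gave an adjusted p under 0.05 (8, 7 and 5 lists). The 18 miRNAs known to be lowered in liver cancer had a median of -0.23 in HCC minus NT, and the separate point near 2.80 in NT minus normal liver is miR-451. Relative to all miRNAs, let-7 and miR-30 in HCC minus NT, miR-30 in NT minus normal liver, and lowered-in-cancer miRNAs in HCC minus normal liver turn with the percentile scalings. These scalings are a single check there, against a median set by dim probes.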

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

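No test in this part was chosen after its result was seen. The 39 probes for miRNAs of mouse herpesviruses, which no comparison used, were looked at for signal in the STAM arrays beyond the normal liver. Among them 1 probe, mcmv-miR-M23-1-3p, was above background on all 5 STAM arrays and not on the normal array. Its signals above the mean of the blank spots were 2.51 and 2.85 in NT 1 and 2, 3.36, 2.86 and 2.79 in HCC 1, 2-1 and 2-2, and -1.21 in normal liver, where the SD of the blanks was 1.02 to 1.52 per array. In all, 10 viral probes were above background in normal liver, 19 and 15 in NT 1 and 2, and 15, 18 and 18 in HCC 1, 2-1 and 2-2. On at least 2 arrays 51.3% of viral probes passed, against 56.0% of mouse probes, with median signals above the blanks of 4.11 and 4.69. Whether the viral signal is specific was not tested, so above background is not read here as presence of a miRNA. The brightest viral probe, mcmv-miR-M23-1-5p, lay between 216 and 398 on every array, at 280 in normal liver.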

How the results depend on the processing

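The scaling made before the offset was chosen after seeing the data. All other alternatives were planned and run, except that the list test was not run with the random block; both blocks by label number apply to HCC against NT alone. Counts of miRNAs that passed limma's test were 0 for HCC against NT, 1 for NT against normal liver and 1 for HCC against normal liver, always higher. With median scaling they were 20 (12 higher, 8 lower), 17 (all higher) and 39 (33 higher, 6 lower), and with upper-quartile scaling 15 (8 higher, 7 lower), 9 (7 higher, 2 lower) and 498 (14 higher, 484 lower). An offset added before scaling moves all dim probes of an array together, by the construction of these 2 settings. Relative to all miRNAs these 2 settings give the same values, so they are not separate checks of a direction. Scaled before the offset, the counts were 3 (all lower), 2 and 1. The authors' values, on 348 probes, gave 0, 5 (all higher) and 14 (13 higher, 1 lower). No filter gave 1, lower, in HCC against NT, and the trended and robust prior gave 3 (2 higher, 1 lower), 5 (4 higher, 1 lower) and 8 (4 higher, 4 lower). Against normal liver 0 passed with the chip as a block (68 for NT and 46 for HCC at an unadjusted p under 0.05) and 0 in fits of the compared groups alone (57 and 95), settings that leave fewer residual degrees of freedom. Leaving out 1 array gave 0 in HCC against NT and 0 to 1 in each comparison with normal liver.

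Of lists, camera called 8 (1 higher, 7 lower), 7 (5 higher, 2 lower) and 5 (2 higher, 3 lower) in the 3 comparisons. Median scaling gave 3 (1 higher, 2 lower), 8 (all higher) and 7 (6 higher, 1 lower), and upper-quartile scaling 3 (1 higher, 2 lower), 7 (all higher) and 2 (all higher). In HCC against NT cyclic loess gave 6 and scaling before the offset 7, all lower. The blank level subtracted gave 5 in HCC against NT and 4 in NT against normal liver, the authors' values 5, 4 and 2, the filter on all arrays 2 in HCC against normal liver, and the fit of these groups alone 3. With the chip as a block 4 (1 higher, 3 lower) were called in HCC against NT and 2 in HCC against normal liver. These rest on a single pair of arrays or, against normal liver, on such pairs chained through NT, and cannot show that a call held. Camera with an estimated correlation called 0 in each comparison, and fry 1, 0 and 0. Leaving out 1 array gave 4 to 8, 6 to 8 and 3 to 5 lists; without NT 1 or NT 2, the NT array left was assumed to vary like the other groups.

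With the label number as a replicate block, 0 miRNAs (57 at an unadjusted p under 0.05) and 6 lists were called in HCC against NT. It ended the calls of miR-17-92 and bile duct markers and changed no other call. As a random block the label number gave 0 miRNAs (54), as did averaging HCC 2-1 and 2-2 (48). Averaging called 7 lists, all lower, and ended the call of miR-17-92.

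The list test reversed for let-7 in HCC against NT, pointing up at medians of -0.0809 with median and -0.21 with upper-quartile scaling. In HCC against normal liver it reversed for miRNAs lowered in liver cancer (-0.17 and -0.51), let-7 (0.34 and 7.38e-05) and, with median scaling alone, miR-29 (0.26) and mesenchymal markers (0.11). With upper-quartile scaling miR-155 (-0.60), miR-142-3p (-0.48), miR-486/miR-3107 (-0.55) and miR-144 (-0.58) passed as lower in HCC than normal liver; this scaling moved the median of all miRNAs by -0.61 there, and relative to it they lay 0.01, 0.13, 0.06 and 0.03 above. Beyond the offset's effect the cause was not tested. Over all alternatives, 2225 values of named miRNAs kept their direction and side of the threshold, 76 passed newly, 12 no longer passed, 75 changed direction without a call and 4 reversed. For lists these were 736, 10, 114, 65 and 8. Most of the 2225 were values that passed in neither fit, since miR-451 alone was called in the main fit. Its call was kept in 13 of 19 alternatives in each comparison with normal liver. A median signal of 4.69 above the blanks limits what most of the 613 probes can show.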

Other observations

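No test in this part was chosen after its result was seen; the miRNAs of the next paragraph were picked after their values were seen and carry no test.

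The HCC samples differed among themselves in several miRNAs, of which miR-122 alone is in the list of liver-enriched miRNAs. MiR-122 lay at 11.61 in HCC 1, 12.38 in HCC 2-1 and 12.65 in HCC 2-2, with signals above the blanks of 2707, 4624 and 7344. Its star strand miR-122* was lower in each HCC sample (7.68, 7.91 and 8.42) than in either NT sample (mean 8.66). HCC 1 was the highest of the HCC samples in miR-125b-5p (7.99, against 7.60 and 7.05), miR-34a (7.83, against 6.82 and 7.22) and miR-378 (8.03, against 7.17 and 7.61), whose gene lies within that of the metabolic coactivator Ppargc1b in GRCm38.p6. The related miR-378b was at 8.34, 7.27 and 7.71 in the same samples. HCC 1 lay on chip 2 at gain 41, and HCC 2-1 and 2-2 on chip 3 at gain 39 with another label number. Between HCC 1 and the others, sample, label number, chip and gain cannot be told apart.

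Most lists called between HCC and NT were lower in HCC, 7 of 8, and a change that depends on brightness alone, or a lower level of long-known miRNAs as a class, could give such a pattern. Against brightness, 5 of the 7 lay below percentile 2.5 of 10000 random lists matched on mean level, from 0 for bile duct to 2.41 for mesenchymal markers. These 5 are not separate checks, since the list of miRNAs lowered in liver cancer shares members with each of the others. Random members were also drawn singly, without the correlation between members of a list. They came from the 20 neighbours in rank on each side, with the member itself and others of its list included. Random lists could therefore hold members of the list tested. For let-7 (3.68) and miR-30 (8.36) brightness stays open. Against the class, 6 of the 7 stayed called when only the 237 miRNAs numbered up to 500 without a star were tested, all but bile duct markers (adjusted p 0.135). A scanner gain of 39 to 41 in HCC and 38 in NT, the scaling (3 of the 8 lists kept with median or upper-quartile scaling) and correlation between members (0 called when it was estimated) stay open. So do a different mix of cells in tumours and a change within tumour cells, which were not tested.

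MiR-451 was higher on all 5 STAM arrays than in the 1 normal liver, and more red blood cells in the STAM samples may account for it. In that case miR-144 and miR-486, the other erythroid miRNAs tested, would be higher too, and 0 of the 2 lay above normal liver by more than 2 SE in both NT and HCC. MiR-144 lay 0.945 and 0.704 SE above normal liver in NT and HCC, and miR-486/miR-3107 2.18 and 1.88 SE. Both had signals under 12 above the blank spots on every array, too near the floor to decide for or against red blood cells. An effect of that single normal array and a biological difference of STAM mice stay open.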
